A study of Homo sapiens with 6 samples.

How the data were processed

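CITE-seq libraries of T cells from 3 donors were analysed. Each donor gave 1 gene expression library and 1 library of antibody tags and tissue hashtags, 6 libraries in all, and the cells carried 5 tissue labels (pancreas, islets, spleen, pancreatic lymph node and small intestine) over 7, 6 and 5 hashtags in donors 1, 2 and 3. All tissues of a donor share a library, so tissues were compared within donors and donor was also the library. The labels' protocols describe an enzyme perfusion and digestion of the pancreas that differs from the digestion of the other tissues. Each tissue had its own preparation, so that tissue and preparation cannot be separated.

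The deposited matrices hold raw UMI counts of 36601 genes, antibody tags and hashtags for 728640, 610421 and 592765 unfiltered barcodes. The matrix header names Cell Ranger 4, and the submitters' processing notes name Cell Ranger 6.0, GRCh38 and Seurat; the annotation release is not given in the sources used here. The authors' cell tables keep 5262, 3365 and 2725 cells, all singlets by hashtag, with 204 to 2499 genes detected. They also hold the deposited percent of mitochondrial UMIs per cell, at most 5.00, and a deposited hashtag margin score. A wider deposited table of donor 1 lists 7945 cells before the authors' selection. The deposited antibody counts equalled the matrix in 100% of values. The gene total recomputed from the matrix equalled the deposited total exactly in 80.9%, 75.0% and 77.8% of cells, and the largest relative difference was 0.332%, 0.690% and 0.322%. Deposited tables named as RNA counts held, in the first 200 rows that were checked, 92.6% to 93.9% of values below 0 and none above 10, so they were taken as scaled values and not used. One donor 1 hashtag read as islets in the labels may carry an error of the source that could not be settled here.

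Over all barcodes the libraries held 43297410, 38427493 and 41826860 gene UMIs, of which the kept cells held 13585779, 10864884 and 8307366, or 31.4%, 28.3% and 19.9%. Kept cells held 13992825, 1091305 and 1298742 antibody counts. Of the antibodies, 137 occur in every panel, 7 of them isotype controls. Depth sets the precision: a gene with 0 UMIs in a group is limited to the level that 3 counts of the group's total would give, and such limits cover counting error only.

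T cells were cells with at least 1 UMI of CD3D, CD3E or CD3G. CD8 T cells had a CD8A or CD8B UMI, no CD4 UMI and a CD4 tag below the donor's threshold. CD4 T cells had no CD8A or CD8B UMI, a CD8 tag below threshold, no gamma-delta constant-chain transcript and fewer than 2 NK or innate lymphoid markers. These rules gave 6227 CD8 and 3985 CD4 T cells, and left 1140 cells (10.0%) unassigned. Requiring a CD4 transcript or tag was set aside after cell counts were seen, and before any gene was tested, because it left 1 donor with fewer than 20 pancreas cells. Tag thresholds were the valley of the density of log2 counts, with a bandwidth of 0.75, or Otsu's threshold for CD8 and CD69 in donor 2, which had no valley. Bandwidth and fallback were chosen after seeing the tag counts. Thresholds in donors 1, 2 and 3 were 30.6, 4.43 and 5.50 counts for CD4, 2.84, 1.45 and 2.20 for CD8, 26.9, 3.47 and 7.69 for CD69 and 16.1, 7.94 and 5.41 for CD103. CD8A, CD8B and CD4 define the subsets and are no finding.

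UMIs and antibody counts were summed per donor, tissue and subset where at least 20 cells were present. Genes and proteins were tested in edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F-test) with all tissues in 1 fit per subset and donor as a block, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The pairing comes from the donors: deviations from tissue means correlated on average at 0.191 (CD8) and 0.124 (CD4) within a donor, and at −0.0958 and −0.0613 between donors, across genes. Because each tissue was centred over its 3 donors, the values between donors follow from those within a donor. The 3 tissue contrasts of a subset share their pancreas sums and were not compared with each other. CD8 and CD4 T cells of the pancreas were compared in a fit with the donor block, and the difference between their tissue contrasts was tested as an interaction over 7317 genes. Shares of cells were compared by two-sided exact sign-flip tests over the 3 paired donors, whose smallest p is 0.25.

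Before the data were examined, 18 lists of T cell genes and 10 lists of markers of other cell types were fixed, and 18 lists were tested per contrast. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. None of the 162 list tests passed with an estimated correlation, where the lowest adjusted p was 0.0558. Genes named in the text are the 8 largest rises and 8 largest falls per contrast past the threshold, with the same sign in every donor and a mean log2 CPM of at least 5. T cell receptor, immunoglobulin, mitochondrial, ribosomal, sex-linked and HLA-DRB genes, clone names and markers of other cell types were left out. Up to 4 members with the smallest p per list, and the 8 largest rises and falls among proteins without isotype controls, were added. Genes at 0 and genes that differed between subsets were named after their values were seen. Some genes and proteins that these rules select are not reported here.

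The fit was tested on simulated counts with known changes of 1 or 2 on the log2 scale. Changes of 2 were made in 97, 93 and 96 of 6589, 6596 and 6594 genes in the CD8 comparisons with spleen, lymph node and small intestine. They were recovered for 75.3%, 77.4% and 81.2% of these. In the CD4 comparisons 94, 91 and 94 of 6587, 6694 and 6739 genes were changed by 2, and 50%, 63.7% and 60.6% were recovered. In CD8 against CD4, 82 of 6262 genes were changed by 2, and 54.9% were recovered. Changes of 1 were recovered for 6.38%, 7.53% and 23.4% of genes in CD8, 4.30%, 6.74% and 5.38% in CD4 and 3.37% in CD8 against CD4. Between 0% and 4.82% of gene calls were false. Among 137 proteins, 10 were changed by 2 and 10 by 1 in each comparison. Changes of 2 were recovered for 80% to 100% and up to 16.7% of calls were false. A change of 1 was recovered for 10% to 70%. In the simulated genes a change of 1 mostly went uncalled. The simulation used 1 preset spread and few changed genes, so its shares need not hold for the real data. There, 631 of 1231 calls in CD8 against small intestine exceeded 1 on the log2 scale and the others did not.

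Alternatives changed 1 choice at a time: DESeq2 1.42.0 size factors or its Wald test, no filter on low counts, no donor block, a fit of 2 tissues alone, each donor left out, at least 500 genes detected per cell (the limit of 10% mitochondrial UMIs removed no cell), cells with at least 2 markers of a second lineage left out, equal cell numbers per tissue, subsets by transcripts alone, and receptor, ribosomal, mitochondrial and contamination genes left out. For proteins, isotype scaling and limma on centred log-ratios were run. Tag thresholds were raised 1.5 times, and cells were thinned to 2172, 250 and 347 tag counts, leaving out 1315, 835 and 677 shallower cells in donors 1, 2 and 3. Added after seeing the data were the islets comparisons, islets summed into the pancreas, CD4 evidence required, the CD8 share by the same rules without tags, and 1 small intestine hashtag (labelled EL) alone. Requiring CD4 evidence and subsets by transcripts alone also changed the number of donors, since sums under 20 cells were left out. Pancreas CD4 sums then remained in 2 donors and in 1 donor. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.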

Results

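T cells from the pancreas, spleen, pancreatic lymph node and small intestine of 3 donors were measured by CITE-seq, a single-cell assay that counts transcripts and antibody tags bound to surface proteins in the same cell. All tissues of a donor were stained with tissue hashtags, pooled and run as 1 gene expression library and 1 tag library, so that the series holds 6 libraries. The deposited cell tables held 5262, 3365 and 2725 cells for donors 1, 2 and 3. The tissue labels placed 2971 cells in the pancreas, 1081 in the spleen, 2535 in the pancreatic lymph node and 4235 in the small intestine. A further 530 cells carried the islets label and were kept apart from the pancreas, with sums of their own in the joint fits. Median depth was 2505, 3152 and 3064 gene UMIs per cell in donors 1, 2 and 3, and 2557.5, 302 and 436 antibody counts per cell. Antibody depth therefore differed between donors, and every comparison was made within donors. UMIs were summed per donor, tissue and subset before testing, which gave 30 sums of 26 to 1913 cells and 75460 to 4796181 gene UMIs. Values in parentheses after gene or protein names are log2 fold changes, pancreas over the named tissue, ± standard error (SE) from the model. This SE comes from the joint fit of all tissues and is not the spread of the 3 donors' own differences. For the CD49a tag in CD4 T cells against spleen, for example, the SE was 0.38 and the SD of those differences 1.13. For a gene list, the first count of members is over all genes tested, the second is adjusted over the list alone, and "by both counts" means that these are equal. Of the p-values in parentheses after a list, the one not named otherwise is camera's adjusted p. CPM denotes counts-per-million as a mean over donors. For single genes these carry the normalization of the fit, so that a level can differ between fits, and for marker groups and lists they are shares of the gene UMIs of a sum. Macrophages, which the series title also concerns, were not analysed here.

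The first question was which T cell lineage the pancreas holds. CD8 T cells made up 81.1% ± 9.44 of pancreas T cells (SD, n = 3), 80.7% ± 17.7 of those of the small intestine, 31.1% ± 17.2 of those of the spleen and 21.3% ± 5.29 of those of the pancreatic lymph node. The CD8 share of the pancreas exceeded that of the spleen by 50.0 ± 7.86 percentage points and that of the lymph node by 59.8 ± 14.7 points, and both differences had this sign in every donor. Their two-sided exact sign-flip p of 0.25 is the smallest that 3 donors allow. Pancreas and small intestine differed by 0.442 ± 18.1 points (exact sign-flip p = 1), less than the spread between donors. The sign of this last difference depended on the donors, at −9.69 points without donor 1, 7.68 without donor 2 and 3.34 without donor 3. It was −5.18 points with 1 of the small intestine hashtags alone and 5.99 points when CD4 T cells had to show CD4 itself. Cells left unassigned, which are outside these shares, made up 4.57%, 10.3% and 8.41% of pancreas cells and 22.3%, 31.9% and 32.1% of spleen cells in donors 1, 2 and 3. In donor 1, the wider table before the authors' selection held 2585 pancreas, 1406 spleen, 1366 lymph node and 2298 small intestine cells. The kept cells of this donor were 2451, 166, 283 and 2104 in that order. The selection thus fell unevenly on the tissues, and its effect on these shares was not tested. The CD4 tag, which helps to set the subsets, was low in the pancreas: in T cells with a CD4 UMI and no CD8 UMI its median was 31, 1 and 13 counts in donors 1, 2 and 3, against 59, 17 and 20 in the spleen. The same rules without any tag, chosen after seeing the data, gave 49.5 points from the spleen, 58.5 from the lymph node and 1.74 from the small intestine. With subsets set by transcripts alone, the pancreas exceeded the spleen by 33.1 points and the lymph node by 32.2 points.

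**Figure D1:**
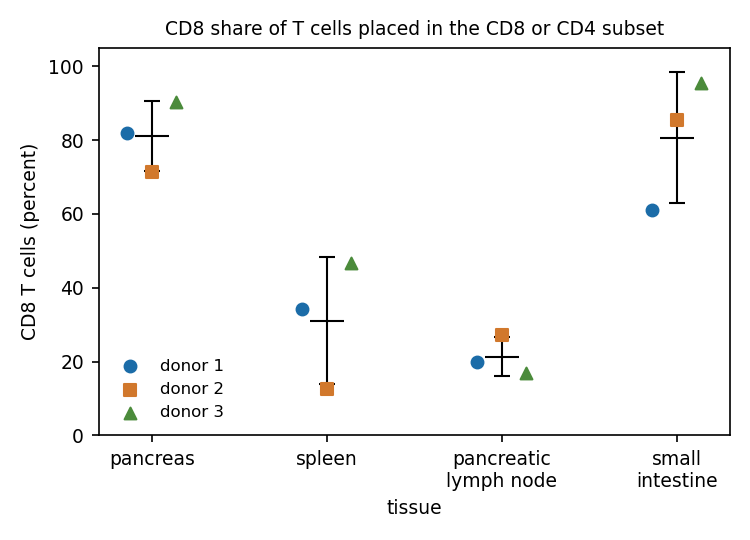
Percentage of CD8 T cells among CD8 and CD4 T cells (vertical axis) in each tissue (horizontal axis), with 1 point per donor and the mean ± SD as lines. The pancreas mean of 81.1% lies close to that of the small intestine (80.7%), and in every donor the pancreas lies above the spleen and the pancreatic lymph node.

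The evidence behind each cell differed between tissues. CD8 T cells resting on a single CD8A or CD8B UMI made up 6.50% ± 1.25 in the pancreas, 15.5% ± 3.68 in the spleen, 15.4% ± 3.03 in the lymph node and 9.13% ± 5.38 in the small intestine (SD, n = 3). The CD4 subset was defined by the absence of CD8, of a gamma-delta constant-chain transcript and of natural killer (NK) features. A CD4 transcript or tag was present in 55.4% ± 19.3 of its cells in the pancreas, 90.2% ± 7.05 in the spleen, 94.9% ± 4.90 in the lymph node and 74.4% ± 13.4 in the small intestine (SD, n = 3). The TCR.Vd2 tag, which marks a gamma-delta T cell type and was chosen after its values were seen, took 4839 ± 6133 CPM, here of antibody counts, of this subset in the pancreas and 690 ± 77.1 in the spleen (SD, n = 3). With a CD4 transcript or tag required, these levels were 743 (n = 2) and 689 (n = 3). The low CD4 tag of the pancreas would itself lower the share of cells with evidence of CD4. Part of the pancreas CD4 subset thus lacked direct evidence of CD4 and may be gamma-delta T cells, and the number of its cells was low in 2 donors, at 426, 45 and 31 cells in donors 1, 2 and 3.

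Markers of other cell types were low in the summed T cells, with an exception in the spleen. B cell markers took 249 ± 215 CPM (SD, n = 3) of CD8 T cells from the spleen, against 49.0 ± 26.5 CPM in the pancreas, 64.5 ± 22.9 in the lymph node and 15.4 ± 8.89 in the small intestine. In CD4 T cells these markers took 86.3 ± 62.2 CPM in the pancreas, 86.2 ± 22.9 in the spleen, 52.7 ± 16.8 in the lymph node and 34.6 ± 20.4 in the small intestine. Transcripts of acinar digestive enzymes, which are abundant in digested pancreas, took 31.3 ± 34.1 CPM of pancreas CD8 T cells and 35.0 ± 47.8 CPM of pancreas CD4 T cells. Plasma cell transcripts took 35.1 CPM of CD8 T cells in the pancreas and 82.5 CPM in the spleen, and 17.1 and 22.5 CPM of CD4 T cells. Myeloid markers took 27.1 CPM in the pancreas, 64.1 in the spleen and 70.8 in the lymph node among CD8 T cells, and 15.0, 46.9 and 66.2 CPM among CD4 T cells. Endothelial and stromal markers took 29.4 CPM of pancreas CD8 T cells and 9.05 CPM of pancreas CD4 T cells. Duct markers stood at 2.81 and 4.31 CPM, islet endocrine markers at 5.39 and 4.31 CPM, intestinal epithelial markers at 7.42 and 1.32 CPM, mast cell markers at 0.505 and 0.992 CPM and red cell markers at 2.18 and 7.51 CPM of these 2 subsets.

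Tissue-resident memory T cells are commonly recognised by surface CD69, a C-type lectin that opposes S1PR1-driven exit, and CD103, the integrin that binds E-cadherin on epithelium. CD69 tags were found on 8.14% ± 13.9 of pancreas CD8 T cells, 20.1% ± 5.64 of those of the spleen, 33.5% ± 13.6 of those of the lymph node and 86.8% ± 19.6 of those of the small intestine (SD, n = 3). The pancreas lay −78.6 ± 17.9 points from the small intestine (exact sign-flip p = 0.25, negative in every donor), −25.3 ± 23.8 points from the lymph node (p = 0.25, exact) and −11.9 ± 19.3 points from the spleen (p = 0.5, exact). CD103 tags were found on 58.8% ± 41.3 of pancreas CD8 T cells, with donors between 12.5% and 91.7%, on 15.0% ± 16.8 in the spleen, 27.8% ± 7.69 in the lymph node and 80.6% ± 24.4 in the small intestine. Those differences of the pancreas were 43.8 ± 58.1 points against the spleen (exact sign-flip p = 0.5), 31.1 ± 46.0 points against the lymph node (p = 0.5, exact) and −21.7 ± 17.9 points against the small intestine (p = 0.25, exact). Cells with both tags made up 6.82%, 7.75%, 15.8% and 78.4% of CD8 T cells from the pancreas, spleen, lymph node and small intestine.

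Among CD4 T cells, CD69 tags were found on 6.34% ± 6.45 in the pancreas, 21.5% ± 15.0 in the spleen, 39.6% ± 9.48 in the lymph node and 86.4% ± 15.2 in the small intestine (SD, n = 3). The pancreas lay −15.2 ± 14.2, −33.3 ± 14.1 and −80.1 ± 11.9 points from the other 3 tissues in that order, each with the smallest exact sign-flip p, 0.25. CD103 tags were found on 4.21% ± 4.77 of pancreas and 60.8% ± 21.7 of small intestine CD4 T cells, −56.6 ± 19.3 points apart (p = 0.25, exact), with 0.746% ± 0.436 in the spleen and 0.695% ± 0.560 in the lymph node. Both tags were seen on 1.08% in the pancreas and 59.8% in the small intestine. Among transcripts, CD69 stood at 679 CPM in pancreas CD8 T cells, 1071 in the spleen, 1743 in the lymph node and 1641 in the small intestine. ITGAE, which encodes CD103, stood at 155, 70.8, 85.4 and 182 CPM. Pancreas CD8 T cells with an ITGAE UMI made up 33.3% ± 1.85, from 31.2% to 34.7% over donors (SD, n = 3). The wide spread of the CD103 tag between donors thus had no counterpart in this transcript share, and its cause was not tested. In CD4 T cells CD69 stood at 617, 1406, 1857 and 2223 CPM.

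Single donors moved several of these tag differences by over 1.5 times. For CD69 on CD8 T cells the difference from the spleen was −5.49 points without donor 1, −7.25 without donor 2 and −23.0 without donor 3, and that from the lymph node was −13.4 without donor 2. The CD103 difference on CD8 T cells was 21.0 points from the spleen without donor 1 and 76.5 without donor 2, and 15.6, 57.5 and 20.1 points from the lymph node without donors 1, 2 and 3. From the small intestine it was −12.6 points without donor 2. On CD4 T cells, CD69 differed from the spleen by −6.98 points without donor 1. Some pancreas tags also lay more than 1 log2 below their own transcripts in every donor, relative to the spleen. This held for 7 of 60 tag and gene pairs in CD8 T cells and 7 of 53 in CD4 T cells, against 2 and 5 pairs for the small intestine, with the genes that define the cells (CD3, CD8 and CD4) left out. CD69 and CD103 were not among these pairs, while CD27 (tag −3.44 and gene −0.57 in CD8, tag −2.93 and gene −0.74 in CD4) and CD99 (tag −2.01 and gene 1.00 in CD8, tag −1.89 and gene 1.00 in CD4) were.

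**Figure D2:**
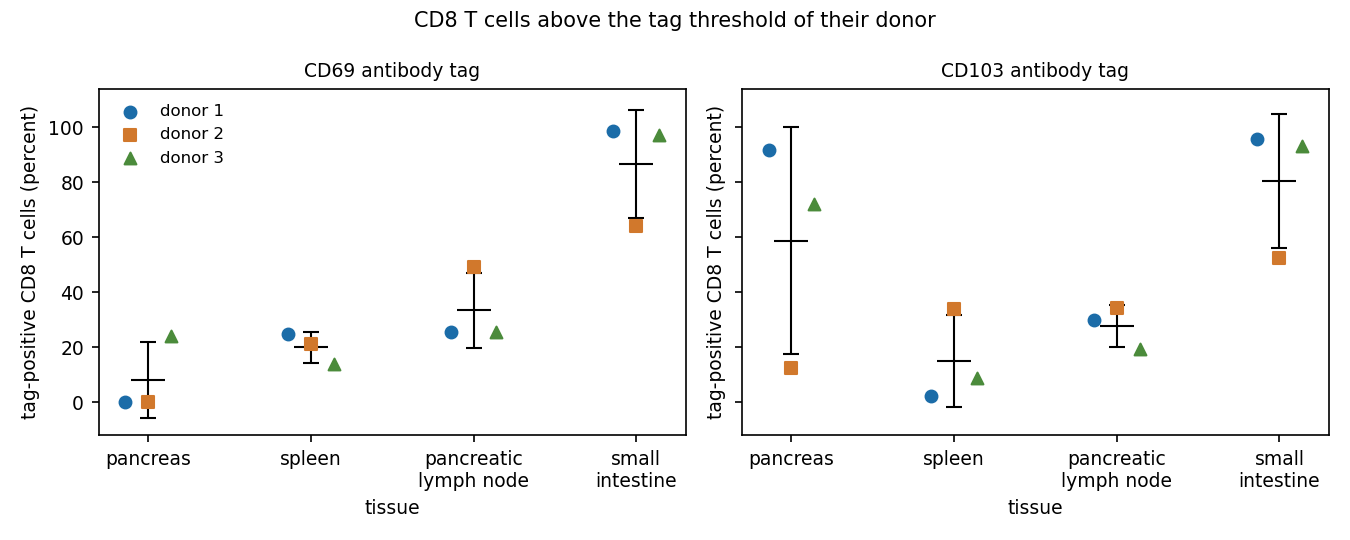
Percentage of CD8 T cells above their donor's threshold (vertical axes) for the CD69 tag (left) and the CD103 tag (right) in each tissue (horizontal axes), with 1 point per donor and the mean ± SD as lines. CD69-positive cells average 8.14% in the pancreas and 86.8% in the small intestine, while CD103-positive cells in the pancreas range from 12.5% to 91.7%.

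CD8 T cells of the pancreas and of the spleen differed in genes of tissue residency, recirculation and the naive state. CXCR6, a chemokine receptor of tissue T cells, rose from 31.9 to 263 CPM (3.27 ± 0.36, adjusted p = 4.45e-05), and ITGA1, the CD49a chain that binds collagen, from 7.08 to 67.5 CPM (3.26 ± 0.44). ITGAE (1.25 ± 0.28, adjusted p = 0.0136) and CD101 (1.76 ± 0.43) rose as well, while CD69 (−0.67 ± 0.26, adjusted p = 0.169) did not pass. KLF2, a transcription factor that drives S1PR1, stood at 54.2 CPM against 906 (−4.62 ± 0.47), and S1PR1 (−3.99 ± 0.62) fell with it. LEF1 (−4.88 ± 0.49) and TCF7 (−2.62 ± 0.31), transcription factors of naive and stem-like T cells, and CCR7 (−4.19 ± 0.56), the lymph node homing receptor, were also lower.

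The residency list had 5 of 13 measured members higher and none lower over all genes, and 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.68e-05; adjusted p = 0.0558 with an estimated correlation). In the egress list 8 of 10 members fell by both counts (camera adjusted p = 3.36e-10; adjusted p = 0.0558 with an estimated correlation). Naive and central memory genes fell for 9 of 10 by both counts (2.42e-11; adjusted p = 0.0558 with an estimated correlation). Tissue repair genes rose for 3 of 11 members, and 5 adjusted over the list alone (1.03e-04 by camera; adjusted p = 0.0558 with an estimated correlation). Among them were CAPG, an actin-capping protein (3.45 ± 0.62), and the galectin LGALS3 (2.37 ± 0.41). Inhibitory receptors rose for 3 of 7 members, 5 adjusted over the list alone (0.0138 by camera; adjusted p = 0.118 with an estimated correlation). PDCD1, which encodes PD-1 (2.50 ± 0.66), and CD96 (0.76 ± 0.17) were among them. Circulating effector genes fell for 4 of 9, 7 adjusted over the list alone (4.94e-05; adjusted p = 0.101 with an estimated correlation). They included FCGR3A, the Fc receptor CD16 (−2.63 ± 0.71), PLEK (−3.02 ± 0.57) and ZEB2 (−1.80 ± 0.44). Of 12 cytotoxic granule genes, none passed by either count, with GNLY at −1.42 ± 0.53 (adjusted p = 0.152) and NKG7 at −0.93 ± 0.47 (adjusted p = 0.319).

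In the immediate early and heat shock list 11 of 22 members fell and 1 rose (14 and 3 adjusted over the list alone; camera adjusted p = 7.32e-07, adjusted p = 0.154 with an estimated correlation). FOS (−2.87 ± 0.56), FOSB (−2.74 ± 0.39), JUNB (−2.37 ± 0.36), IER2 (−2.63 ± 0.32) and ZFP36 (−1.59 ± 0.22), transcripts that appear within minutes of stimulation, fell. HSPA1A, a heat shock chaperone, rose from 63.6 to 1551 CPM (4.74 ± 1.18). The whole list took 12566 ± 6310 CPM in the pancreas and 24820 ± 6610 CPM in the spleen (SD, n = 3). In donor 1 it took 4878 CPM of cells with the crude and 8209 CPM of cells with the exocrine pancreas hashtag. Antigen presentation genes fell for 6 of 8, 7 adjusted over the list alone (6.49e-05; adjusted p = 0.0786 with an estimated correlation), among them CD74 (−1.86 ± 0.31), HLA-DRA (−3.10 ± 0.58) and HLA-DPA1 (−1.03 ± 0.18). These genes are abundant in B cells. With cells carrying markers of a second lineage left out, CD74 stood at −0.80 (adjusted p = 0.181), HLA-DRA at −0.11 (adjusted p = 0.992) and HLA-DPA1 at −0.39 (adjusted p = 0.494). CD79A, a B cell marker, fell (−4.64 ± 0.57) but stood at −2.89 (adjusted p = 0.0838) without those cells. Interferon response genes fell for 2 of 13 by both counts (0.0154; adjusted p = 0.0734 with an estimated correlation). Of 4 cell cycle genes 1 rose by both counts, HMGB2 (1.64 ± 0.26; 0.0138, adjusted p = 0.0734 with an estimated correlation). The 8 other lists (cytotoxic, cytokine, type 17, follicular helper, gut homing, NK receptor, lipid and B cell contamination) had camera adjusted p between 0.0819 and 0.966. The gut homing list had a median of 0.14, a mean of −0.09 and an upward test, and the lipid list a median of 0.23, a mean of 0.18 and a downward test. Other large rises were GPR25 (3.87 ± 0.52), KLRC1, an NK receptor subunit (2.70 ± 0.65), CD9, a tetraspanin (2.25 ± 0.37), and ARHGAP18 (2.73 ± 0.55). CCL4 (1.57 ± 0.35) rose and LTB (−2.06 ± 0.40) fell.

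By edgeR's quasi-likelihood test with donor as a block, 330 of 6471 genes passed the threshold, 117 higher and 213 lower in the pancreas. The count was 30 without donor 3, 130 without the donor block and 173 with equal cell numbers per tissue. Spleen sums were small (44, 47 and 115 cells in donors 1, 2 and 3), and 13 of 34 named calls held without donor 3, 28 of 35 without donor 1 and 33 of 35 without donor 2.

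At the surface, CD8 T cells of the pancreas carried more CD49a (2.53 ± 0.30, adjusted p = 2.07e-04), the protein of ITGA1, than those of the spleen. CD279, which is PD-1 (1.12 ± 0.30), CD52 (1.19 ± 0.30) and the integrin chain CD29 (1.07 ± 0.20) were higher too. CD45RA, the long CD45 isoform of naive cells, was lower (−3.49 ± 0.38, adjusted p = 1.92e-04), as were CD328 (−2.34 ± 0.49) and the complement receptor CD35 (−1.62 ± 0.20). The pancreas level of CD328, 211 CPM of antibody counts, lay below those of the isotype controls there (947 to 3435 CPM). CD35 is also a B cell protein, and the B cell tags CD21 (−1.44 ± 0.28), CD20_2H7 (−0.81 ± 0.16), CD32 (−1.18 ± 0.18) and IgD (−1.17 ± 0.37) fell with it, so that B cell material in the spleen sums may account for this fall. CD27 (−3.37 ± 0.43), CD31 (−2.08 ± 0.38) and CD99 (−1.96 ± 0.53) also fell, but their tags lay more than 1 log2 below their transcripts in every donor. Of 137 antibodies, 30 passed, 11 higher and 19 lower; centred log-ratios gave 12 higher and 9 lower. The count was 14 without donor 1 and 15 without donor 2.

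Against CD8 T cells of the pancreatic lymph node, those of the pancreas differed in residency, cytotoxic, recirculation, naive and immediate early genes. Some cytotoxic effectors rose, with PRF1, the pore-forming perforin, at 433 against 72.6 CPM (2.37 ± 0.38), and GZMB at 261 against 38.3 (2.58 ± 0.51). GNLY, which encodes granulysin, stood at 555 against 47.6 CPM (3.59 ± 0.68), and FASLG, the death ligand, was higher (3.31 ± 0.61). CXCR6 rose from 18.6 to 263 CPM (3.54 ± 0.33, adjusted p = 1.34e-06), with ITGA1 (2.77 ± 0.33) and ITGAE (1.03 ± 0.25). CD69, by contrast, fell from 1743 to 679 CPM (−1.43 ± 0.26, adjusted p = 8.58e-04). KLF2 fell from 2075 to 54.2 CPM (−5.46 ± 0.48), with CCR7 (−4.77 ± 0.52), LEF1 (−5.06 ± 0.47) and TCF7 (−3.35 ± 0.29).

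Of 12 cytotoxic granule genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00484, adjusted p = 0.446 with an estimated correlation). Of 13 residency genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; 0.0236, adjusted p = 0.231 with an estimated correlation). Egress genes fell for 8 of 10 by both counts (1.71e-08; adjusted p = 0.0597 with an estimated correlation), and naive genes for 9 of 10, 10 adjusted over the list alone (5.24e-13; adjusted p = 0.0597 with an estimated correlation). NK receptor genes rose for 3 of 9, 4 adjusted over the list alone (0.0107; adjusted p = 0.124 with an estimated correlation), among them KLRC1 (4.42 ± 0.71) and KLRC2 (2.83 ± 0.38). Gut homing and intraepithelial genes rose for 4 of 8 and fell for 1 by both counts (camera adjusted p = 0.0153, adjusted p = 0.124 with an estimated correlation). This list shares ITGAE and ITGA1 with the residency list and KLRC1 and KLRC2 with the NK receptor list. These genes are given as rises above, so the list is not separate evidence. Inhibitory receptor genes rose for 4 of 7 and fell for 1 by both counts (0.0344; adjusted p = 0.228 with an estimated correlation), with PDCD1 higher (1.63 ± 0.48) and TIGIT, another checkpoint receptor, lower (−1.76 ± 0.38). Tissue repair genes rose for 4 of 11 and fell for 1 by both counts (0.0236; adjusted p = 0.217 with an estimated correlation). LGALS1 (3.32 ± 0.40), CAPG (3.22 ± 0.51) and LGALS3 (2.55 ± 0.38) rose and AREG, an epidermal growth factor receptor ligand, fell (−1.67 ± 0.30).

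Immediate early and heat shock genes fell for 17 of 22 and rose for 1 (19 and 1 adjusted over the list alone; camera adjusted p = 4.66e-15, adjusted p = 0.0967 with an estimated correlation). NR4A2, an orphan nuclear receptor induced by receptor signals, fell from 763 to 32.1 CPM (−4.78 ± 0.33), ZFP36 from 4010 to 428 CPM (−3.20 ± 0.23) and JUND from 5127 to 613 CPM (−3.10 ± 0.29). TNFAIP3, the NF-κB feedback inhibitor A20 (−4.19 ± 0.42), and SOCS3, a cytokine feedback inhibitor (−4.18 ± 0.54), fell as well, whereas CISH, its relative, rose (3.57 ± 0.55). XCL1 (1.60 ± 0.35) and KLRB1, which encodes CD161 (2.20 ± 0.39), rose. CD28 (−3.21 ± 0.50) and BCL6, the follicular helper regulator (−3.40 ± 0.47), fell. HOPX (2.94 ± 0.34) and GPR25 (4.15 ± 0.46) were among the largest rises and ZNF331 (−3.96 ± 0.35) among the largest falls. The 9 remaining lists had camera adjusted p from 0.0638 to 0.804. The circulating effector list had a median of 0.32, a mean of −0.13 and an upward test, and the interferon list a median of −0.03, a mean of −0.15 and an upward test.

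In edgeR, 1011 of 6471 genes passed, 369 higher and 642 lower in the pancreas. The count was 645 without donor 1, 275 without donor 3 and 450 with equal cell numbers. Among proteins, CD49a (2.68 ± 0.30), CD29 (1.78 ± 0.20), CD244, a receptor of cytotoxic cells (1.18 ± 0.22), and CD161 (1.02 ± 0.26) were higher. CD45RA was lower (−2.83 ± 0.37). CD27 (−3.89 ± 0.43), CD99 (−3.67 ± 0.54) and CD31 (−2.69 ± 0.37) fell too, with the same deficit of tag against transcript relative to the spleen. Of 137 antibodies 18 passed, 8 higher and 10 lower (8 and 6 with centred log-ratios), 7 without donor 1 and 10 without donor 2.

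CD8 T cells of the pancreas differed from those of the small intestine, a tissue rich in intraepithelial T cells, in cytotoxic and immediate early genes, and residency genes moved both ways. GZMK, a granzyme of memory cells, stood at 225 against 25.5 CPM (3.19 ± 0.69), PRF1 at 433 against 76.9 (2.44 ± 0.33) and GNLY at 555 against 41.6 (3.55 ± 0.59). GZMH (2.65 ± 0.53), GZMB (1.27 ± 0.40) and the cathepsin CTSW (2.72 ± 0.36) rose with them. CXCR6 (3.13 ± 0.25) and ZNF683, the residency regulator Hobit (4.65 ± 0.49), rose. CD69 (−1.39 ± 0.26, adjusted p = 7.03e-04), RGS1, a brake on chemokine receptor signals (−4.05 ± 0.45), and CRTAM (−1.83 ± 0.28) fell, while ITGAE did not pass (−0.20 ± 0.20, adjusted p = 0.539). CCR9, the receptor that guides T cells to the small intestine, had 0 of 5842312 UMIs in pancreas CD8 T cells against 132 CPM in the small intestine. Both are pooled over donors, and with a floor of 3 counts over the group it was at least 257-fold lower, or 39.4-fold without donor 1, which holds most of these UMIs.

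Cytotoxic granule genes rose for 8 of 12 and fell for 1, SRGN (−1.32 ± 0.21), with 9 and 1 adjusted over the list alone (camera adjusted p = 2.12e-05; adjusted p = 0.574 with an estimated correlation). The residency list had 3 higher and 4 lower of 13, 3 and 5 adjusted over the list alone (0.865). Immediate early and heat shock genes fell for 18 of 22 and rose for 1 (19 and 1 adjusted over the list alone; 8.25e-15, adjusted p = 0.302 with an estimated correlation). ATF3, a stress-induced factor, fell from 444 to 14.3 CPM (−5.34 ± 0.43), and NR4A2 (−3.95 ± 0.32), JUND (−3.50 ± 0.30) and ZFP36 (−2.82 ± 0.22) fell, while the heat shock gene HSPA6 rose (2.59 ± 0.85). TNFAIP3 (−5.07 ± 0.44), CSRNP1 (−4.50 ± 0.38), the clock gene PER1 (−4.47 ± 0.31), MYADM (−4.43 ± 0.33) and PMAIP1 (−4.07 ± 0.42) were the largest falls beside these. Antigen presentation genes rose for 2 of 8 by both counts (0.0365; adjusted p = 0.574 with an estimated correlation), with CD27 (1.29 ± 0.30) and HLA-DPA1 (0.71 ± 0.16).

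The remaining 15 lists had camera adjusted p between 0.377 and 0.927, and several held members that moved apart. In the inhibitory list PDCD1 rose from 5.45 to 63.8 CPM (3.69 ± 0.42) and CD160 fell (−2.53 ± 0.31). Among tissue repair genes LGALS3 (2.15 ± 0.32) and LGALS1 (1.64 ± 0.28) rose, while AREG (−3.21 ± 0.30) and the annexin ANXA1 (−2.24 ± 0.41) fell. Within the cytokine list LTB rose (2.03 ± 0.40) and CCL4 fell (−1.45 ± 0.31), and within the type 17 list MAF rose (1.58 ± 0.26) and AHR, the aryl hydrocarbon receptor, fell (−1.75 ± 0.27). The lipid gene PLIN2 (−1.34 ± 0.27) fell, as did KLF2 (−2.20 ± 0.44), TCF7 (−1.48 ± 0.28) and CXCR4 (−0.97 ± 0.19). ITGB2, the chain shared by leukocyte integrins, rose (2.95 ± 0.41). Median, mean and test differed in sign for the naive (−0.08, 0.29, down), circulating effector (0.33, 0.46, down), cytokine (−0.11, −0.01, up), follicular helper (0.57, −0.10, up), NK receptor (−0.21, 0.64, up) and interferon (0.04, −0.17, up) lists.

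Of 6471 genes 1231 passed in edgeR, 460 higher and 771 lower in the pancreas. Counts were 523 without donor 1, 397 without donor 3, 733 without the donor block and 321 with equal cell numbers. CD48 (2.95 ± 0.67), the integrin chains CD11a (2.34 ± 0.49), CD49d (1.34 ± 0.24), CD49a (1.22 ± 0.29) and CD29 (1.16 ± 0.20), the peptidase CD26 (1.49 ± 0.38) and CD279 (1.33 ± 0.30) were among the proteins that rose. CD69 (−3.81 ± 0.68), CD39 (−1.64 ± 0.24), CD7 (−1.64 ± 0.30) and CD101 (−2.17 ± 0.48) fell, as did CD99 (−4.42 ± 0.56) and CD31 (−2.43 ± 0.37). The tags of CD101, CD99 and CD31 lay below their transcripts in the pancreas, and that of CD48 in the small intestine, relative to the spleen. On average the CD11a tag did so in the small intestine (tag −2.01, gene −0.48) and the CD7 tag in the pancreas (tag −0.67, gene 0.72). The small intestine CD69 tag lay above its transcript on average (tag 2.80, gene 0.73), relative to the spleen. Of 137 antibodies 22 passed, 11 in each direction, but 1 without donor 1, 12 without donor 2 and 13 without donor 3.

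Pancreas CD4 T cells differed from those of the spleen in cytotoxic, chemokine, residency, naive and immediate early genes. GZMA rose from 79.5 to 692 CPM (3.35 ± 0.50, adjusted p = 2.06e-04), PRF1 from 60.8 to 328 CPM (2.51 ± 0.39) and GZMK from 44.9 to 285 CPM (2.93 ± 0.63). The chemokine CCL5 rose from 228 to 1121 CPM (2.37 ± 0.51). CXCR6 rose from 2.31 CPM, on 5 spleen UMIs, to 201 CPM (6.37 ± 0.40, adjusted p = 9.32e-11), and XCL1 from 4.54 to 137 CPM (6.24 ± 0.81). CD69 fell from 1406 to 617 CPM (−1.17 ± 0.25, adjusted p = 0.005). KLF2 (−2.05 ± 0.31), S1PR1 (−1.92 ± 0.38), CCR7 (−2.28 ± 0.30) and TCF7 (−1.85 ± 0.28) were lower.

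Cytotoxic granule genes rose for 4 of 11, 8 adjusted over the list alone (camera adjusted p = 5.86e-05; adjusted p = 0.24 with an estimated correlation), CST7 among them (1.99 ± 0.59). Cytokine and chemokine genes rose for 7 of 14 and fell for 1 (8 and 2 adjusted over the list alone; 8.42e-05, adjusted p = 0.0782 with an estimated correlation). CCL4 (3.31 ± 0.92) and TNFSF14, which encodes LIGHT (1.95 ± 0.38), rose and LTB fell (−1.71 ± 0.35). Residency genes rose for 4 of 10 and fell for 1 (5 and 1 adjusted over the list alone; 1.08e-04, adjusted p = 0.0687 with an estimated correlation), including RBPJ (1.46 ± 0.30). Egress genes fell for 5 of 10, 7 adjusted over the list alone (3.13e-05; adjusted p = 0.133 with an estimated correlation). Naive genes fell for 8 of 10, 9 adjusted over the list alone (2.73e-06; adjusted p = 0.0687 with an estimated correlation). Tissue repair genes rose for 3 of 11, 6 adjusted over the list alone (2.12e-04; adjusted p = 0.0687 with an estimated correlation), with CAPG (1.63 ± 0.37) and LGALS3 (1.23 ± 0.30). Inhibitory receptors rose for 3 of 7, 4 adjusted over the list alone (0.00255; adjusted p = 0.194 with an estimated correlation): LAG3 (2.95 ± 0.57), PDCD1 (2.07 ± 0.45) and CD96 (1.08 ± 0.21).

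Immediate early and heat shock genes fell for 12 of 22 and rose for 3 (13 and 3 adjusted over the list alone; camera adjusted p = 1.25e-04, adjusted p = 0.273 with an estimated correlation). FOS (−2.88 ± 0.43), FOSB (−2.82 ± 0.35), IER2 (−2.58 ± 0.31) and JUNB (−2.44 ± 0.31) fell and HSPA1A (4.40 ± 0.98) and HSPA1B (4.28 ± 0.84) rose. By both counts 1 of 8 type 17 genes rose, KLRB1 (1.10 ± 0.29; 0.0128, adjusted p = 0.0809 with an estimated correlation). So did 1 of 7 gut homing genes (0.0326; adjusted p = 0.126 with an estimated correlation) and 1 of 8 NK receptor genes (0.0308; adjusted p = 0.339 with an estimated correlation). The cell cycle list had 1 of 4 members higher by both counts (0.0334; adjusted p = 0.126 with an estimated correlation). The 6 lists left had camera adjusted p from 0.177 to 0.967, and 2 regulatory T cell genes fell, IL2RA (−1.66 ± 0.41) and TNFRSF4 (−2.05 ± 0.52). The follicular helper list (median −0.02, mean 0.04, test down) and the interferon list (0.16, −0.07, up) differed in sign between measures. CEBPD, a transcription factor of the acute phase, was the largest rise by the naming rule (4.81 ± 0.49), with ITM2C (2.60 ± 0.27). TBX21, the Th1 regulator T-bet, rose (3.05 ± 0.67), and PPP1R15A (−2.57 ± 0.36) and SOCS3 (−2.54 ± 0.40) fell.

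Of 6812 genes, edgeR called 397, 141 higher and 256 lower in the pancreas. The count was 119, 144 and 241 without donors 1, 2 and 3, 175 without the donor block, 207 with equal cell numbers and 146 in a fit of these 2 tissues alone. Subsets by transcripts alone left 1 donor with a pancreas CD4 sum, so no count is given for them. Requiring a CD4 transcript or tag left 2 donors in the pancreas. In that fit 176 genes passed, and CXCR6 (7.94), GZMA (4.07) and PRF1 (2.75) kept their rise. Of 35 named calls 30 held then, while PDCD1, IL2RA, TNFRSF4, KLRB1 and CAPG no longer passed. The change of cells and the loss of a donor cannot be told apart here. CD49a (1.91 ± 0.38), CD26 (1.27 ± 0.24), CD103 (1.20 ± 0.32) and CD161 (0.75 ± 0.21) were among the proteins that rose. CD45RA (−2.18 ± 0.26), CD35 (−1.98 ± 0.23), CD7 (−1.15 ± 0.21), CD31 (−1.11 ± 0.30) and CD27 (−2.71 ± 0.53) fell, the CD27 tag more than its transcript in every donor and the CD7 tag on average (tag −1.22, gene 0.15). The B cell tag CD21 (−1.68 ± 0.44) fell beside CD35, from 916 to 181 CPM of antibody counts. These levels lay below those of the isotype control RTK2758, 936 CPM in the spleen and 1552 CPM in the pancreas. B cell transcripts took 86.2 CPM of spleen and 86.3 CPM of pancreas CD4 T cells, so they did not show the spleen excess seen in CD8 T cells. Of 137 antibodies 16 passed, 7 higher and 9 lower. Centred log-ratios gave 5 and 4, and there were 6 without donor 1 and 7 without donor 2.

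Against CD4 T cells of the pancreatic lymph node, those of the pancreas differed in cytotoxic, chemokine, NK receptor, tissue repair, egress, naive and immediate early genes. GZMA stood at 692 against 39.6 CPM (3.98 ± 0.48), PRF1 at 328 against 17.9 (3.89 ± 0.39) and CCL5 at 1121 against 115 (3.26 ± 0.51). CXCR6 rose from 3.78 to 201 CPM (5.37 ± 0.31, adjusted p = 1.43e-11), and CXCR3, the receptor of interferon-induced chemokines, rose (3.19 ± 0.42). CD69 (−1.67 ± 0.25, adjusted p = 3.99e-05) and RGS1 (−2.43 ± 0.49) fell. KLF2 fell from 2307 to 336 CPM (−3.11 ± 0.31), with CCR7 (−2.94 ± 0.29) and TCF7 (−2.17 ± 0.27).

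Of 11 cytotoxic granule genes 10 rose and 1 fell by both counts (camera adjusted p = 1.84e-07; adjusted p = 0.157 with an estimated correlation). Cytokine genes rose for 6 of 14, 8 adjusted over the list alone (5.51e-06; adjusted p = 0.0777 with an estimated correlation), XCL1 (3.49 ± 0.52) and TNFSF14 (4.10 ± 0.41) among them. Egress genes fell for 8 of 10 by both counts (1.09e-05; adjusted p = 0.157 with an estimated correlation) and naive genes for 9 of 10 by both counts (8.16e-08; adjusted p = 0.0777 with an estimated correlation). Tissue repair genes rose for 5 of 11 and fell for 1 (6 and 1 adjusted over the list alone; 4.12e-04, adjusted p = 0.0777 with an estimated correlation). CAPG (3.65 ± 0.40), LGALS1 (3.46 ± 0.38) and LGALS3 (3.06 ± 0.32) rose and AREG (−2.42 ± 0.39) fell. NK receptor genes rose for 3 of 8, 7 adjusted over the list alone (4.12e-04; adjusted p = 0.165 with an estimated correlation), with KLRD1, which encodes CD94 (3.24 ± 0.87). Type 17 genes rose for 2 of 8 and fell for 1 by both counts (0.0407; adjusted p = 0.145 with an estimated correlation), KLRB1 among the rises (2.05 ± 0.29). Immediate early and heat shock genes fell for 17 of 22 (18 lower and 1 higher adjusted over the list alone; 7.72e-11, adjusted p = 0.145 with an estimated correlation). NR4A1 (−4.34 ± 0.74), NR4A2 (−3.92 ± 0.40), FOS (−3.60 ± 0.45) and JUNB (−3.28 ± 0.32) were among them.

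The other 10 lists had camera adjusted p between 0.0747 and 0.985. Among their members PDCD1 (2.05 ± 0.40) and the interferon gene LY6E (1.06 ± 0.23) rose, and TIGIT (−2.91 ± 0.43), CTLA4 (−1.91 ± 0.46), ICOS (−1.30 ± 0.30) and BCL6 (−2.65 ± 0.64), genes of regulatory and follicular helper cells, fell. Outside the lists CEBPD (4.94 ± 0.42), HOPX (3.65 ± 0.30) and CISH (3.59 ± 0.49) rose, and SOCS3 (−3.94 ± 0.37), TNFAIP3 (−3.48 ± 0.41) and ZNF331 (−3.34 ± 0.31) fell. The cell cycle list (median −0.18, mean 0.08, test up) and the lipid list (0.08, −0.26, up) differed in sign between measures.

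Of 6812 genes, 1088 passed, 437 higher and 651 lower. The count was 349 without donor 1 and 513 with equal cell numbers. With CD4 required, which left 2 donors in the pancreas, CXCR6 (5.38), GZMA (4.47) and PRF1 (4.30) kept their rise. In the antibody data CD49a (2.22 ± 0.38), CD26 (1.57 ± 0.24), CD29 (1.22 ± 0.28), CD161 (1.17 ± 0.21), CD103 (1.07 ± 0.31) and the death receptor CD95 (0.95 ± 0.18) rose. CD45RA (−2.40 ± 0.26), CD69 (−1.98 ± 0.59) and CD31 (−1.72 ± 0.30) fell, as did CD99 (−4.05 ± 0.64) and CD27 (−3.30 ± 0.53), whose tags lay below their transcripts. Of 137 antibodies 25 passed, 13 higher and 12 lower, and 5 passed without donor 1.

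CD4 T cells of the pancreas and the small intestine differed in immediate early, cytotoxic, egress and type 17 genes, among others. TNFAIP3 fell from 3587 to 182 CPM (−4.86 ± 0.43), with ATF3 (−4.73 ± 0.50), RGS1 (−4.15 ± 0.48) and CD69 (−1.96 ± 0.25, adjusted p = 5.26e-06). GZMK rose from 13.8 to 285 CPM (4.16 ± 0.68), GZMA from 138 to 692 (2.31 ± 0.47) and PRF1 from 46.4 to 328 (2.29 ± 0.38). CCR7, at 35.1 against 1.88 CPM (4.28 ± 0.54), and LEF1, at 42.0 against 2.61 CPM (4.01 ± 0.52), were higher in the pancreas here. IL17A, the defining cytokine of Th17 cells, had 0 of 1197894 UMIs in the pancreas against 69.4 CPM in the small intestine. Pooled over donors, it was at least 27.7-fold lower with a floor of 3 counts over the group, or 5.66-fold without donor 1, which holds most of these UMIs. CCL20, the ligand of CCR6, fell from 165 to 10.8 CPM (−3.96 ± 0.40).

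Cytotoxic granule genes rose for 7 of 11 and fell for 1, SRGN (−1.38 ± 0.21), by both counts (camera adjusted p = 1.12e-04; adjusted p = 0.247 with an estimated correlation), NKG7 among the rises (2.71 ± 0.81). Type 17 genes fell for 4 of 8, 5 adjusted over the list alone (0.00138; adjusted p = 0.103 with an estimated correlation), with AHR (−1.99 ± 0.27) and RORA (−1.19 ± 0.28). Immediate early and heat shock genes fell for 18 of 22 and rose for 1, HSPA6 (2.52 ± 0.82), with 19 and 1 adjusted over the list alone (3.47e-12; adjusted p = 0.202 with an estimated correlation). Egress genes rose for 5 of 10 and fell for 1 (7 and 1 adjusted over the list alone; 1.66e-04, adjusted p = 0.202 with an estimated correlation). Naive genes rose for 4 of 10 and fell for 1 (6 and 2 adjusted over the list alone; 0.00826, adjusted p = 0.202 with an estimated correlation). NK receptor genes rose for 4 of 8 and fell for 1 (6 and 1 adjusted over the list alone; 0.0249, adjusted p = 0.331 with an estimated correlation), with XCL1 up (2.80 ± 0.49) and CD160 down (−2.73 ± 0.53). Residency genes fell for 3 of 10 and rose for 2 (6 and 2 adjusted over the list alone; 0.0298, adjusted p = 0.202 with an estimated correlation), with RUNX3 down (−1.44 ± 0.25) and CXCR6 up (2.16 ± 0.24). Of 4 cell cycle genes 1 rose by both counts (0.0345; adjusted p = 0.202 with an estimated correlation).

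Camera adjusted p lay between 0.0581 and 0.771 for the 10 other lists. Their members included PDCD1 (1.65 ± 0.40), LTB (1.97 ± 0.38), LGALS1 (1.71 ± 0.36) and HLA-DPA1 (1.80 ± 0.35), which rose. ANXA1 (−2.39 ± 0.28), AREG (−3.01 ± 0.40), CD28 (−1.14 ± 0.30) and the lipid gene PLIN2 (−1.06 ± 0.29) fell. CTSW (3.39 ± 0.43), the integrin chains ITGB2 (2.69 ± 0.33) and ITGB1 (2.31 ± 0.38) and the metallothionein MT2A (3.02 ± 0.65) were further rises. CSRNP1 (−4.35 ± 0.43), PER1 (−4.22 ± 0.37), PPP1R15A (−4.13 ± 0.36) and MYADM (−3.87 ± 0.30) were further falls. Signs differed between median, mean and test for the cytokine (−0.30, −0.06, up) and interferon (−0.10, −0.15, up) lists, and the inhibitory list had a median of 0.165, a mean near 0 and an upward test.

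In edgeR 727 of 6812 genes passed, 238 higher and 489 lower. The count was 107 without donor 1, 381 without the donor block, 283 with equal cell numbers and 453 in a fit of these 2 tissues alone. With CD4 required, which left 2 donors in the pancreas, GZMA (2.35), PRF1 (2.21) and CXCR6 (2.05) kept their rise. Among proteins CD48 (2.11 ± 0.52), CD11a (1.97 ± 0.33), CD26 (1.36 ± 0.24), CD49d (1.33 ± 0.26) and CD82 (1.00 ± 0.17) rose. Relative to the spleen, 3 of these tags lay on average more than 1 log2 below their transcripts in the small intestine. They were CD48 (tag −1.92, gene −0.16), CD11a (tag −1.44, gene −0.24) and CD49d (tag −0.73, gene 0.32), while CD26 and CD82 did not. CD69 (−3.39 ± 0.61), CD103 (−2.95 ± 0.33), its partner integrin β7 (−1.38 ± 0.21), CD101 (−2.12 ± 0.23), CD7 (−1.63 ± 0.21), the ectoenzyme CD73 (−1.63 ± 0.40) and CD99 (−4.18 ± 0.65) fell, the CD99 tag lying below its transcript. The pancreas CD7 tag also lay below its transcript on average (tag −1.22, gene 0.15, relative to the spleen). Small intestine tags of CD69 (tag 3.09, gene 0.98), CD103 (tag 4.22, gene 1.47) and integrin β7 (tag 1.94, gene −0.52) lay above their transcripts on average, relative to the spleen. The integrin β7 transcript stood at 0.07 in the pancreas by this measure, so that its lower tag had no counterpart in the transcript. Of 137 antibodies 18 passed, 8 higher and 10 lower, and 4 passed without donor 1.

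**Figure D3:**
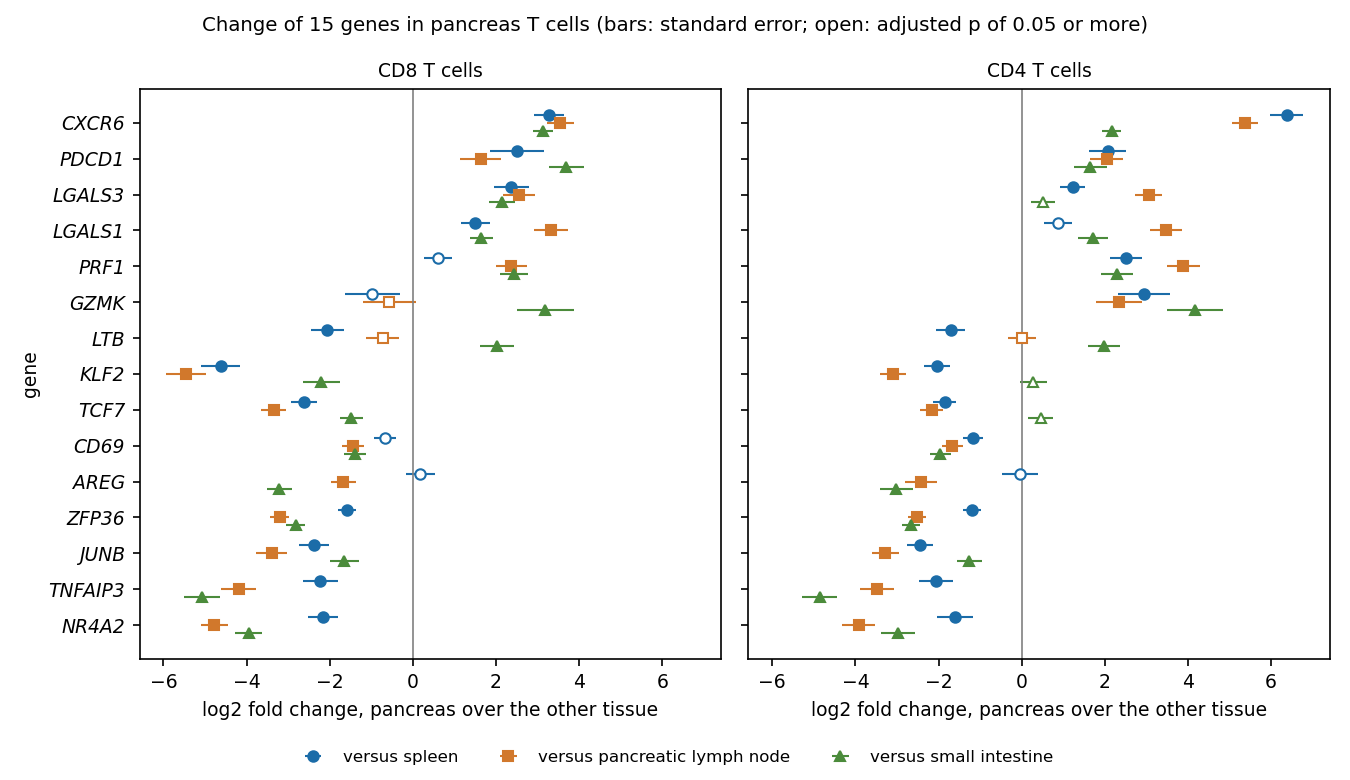
Log2 fold change of pancreas over each other tissue ± SE (horizontal axes) for 15 named genes (vertical axes) in CD8 T cells (left) and CD4 T cells (right), with open symbols where the adjusted p did not pass 0.05. CXCR6 and PDCD1 lie above 0 and ZFP36, JUNB, TNFAIP3 and NR4A2 below 0 in all 6 comparisons.

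Within the pancreas, CD8 and CD4 T cells were compared directly, and values in parentheses here are log2 fold changes of CD8 over CD4. CD8 T cells carried more transcripts of several NK receptors, with KLRC1 at 533 against 19.1 CPM (4.91 ± 0.28, adjusted p = 3.16e-07). KLRK1, which encodes NKG2D (3.52 ± 0.25), KLRC2 (2.84 ± 0.32), KLRC4 (3.67 ± 0.48) and KLRD1 (1.89 ± 0.23) were higher as well. ZNF683 stood at 143 against 2.94 CPM (4.50 ± 0.36), and ITGA1 (1.85 ± 0.30), CRTAM (2.89 ± 0.39), RUNX3 (0.98 ± 0.19) and CD101 (1.69 ± 0.34) were higher in CD8 T cells. KLF2 (−2.85 ± 0.24), S1PR1 (−1.97 ± 0.42), TCF7 (−1.54 ± 0.24) and the checkpoint receptor CTLA4, at 3.52 against 50.6 CPM (−4.37 ± 0.47), were higher in CD4 T cells. Cells with NK markers were excluded from the CD4 subset, which may add to the NK receptor difference and was not tested.

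Of 8 NK receptor genes 4 were higher in CD8, 5 adjusted over the list alone (camera adjusted p = 9.37e-04; adjusted p = 0.264 with an estimated correlation). Residency genes were higher for 5 of 13 (6 higher and 1 lower adjusted over the list alone; 3.14e-04, adjusted p = 0.264 with an estimated correlation). Gut homing genes were higher for 3 of 7, 5 adjusted over the list alone (3.38e-04; adjusted p = 0.264 with an estimated correlation), and cytotoxic genes for 1 of 12, CTSW (1.22 ± 0.19), with 5 higher and 1 lower adjusted over the list alone (0.0197; adjusted p = 0.388 with an estimated correlation). GZMB stood at 1.75 ± 0.40 (adjusted p = 0.0614). The gut homing list shares ITGAE and ITGA1 with the residency list and KLRC1 and KLRC2 with the NK receptor list, so these counts overlap. Lower in CD8 were 3 of 9 egress genes, 6 adjusted over the list alone (3.31e-06; adjusted p = 0.281 with an estimated correlation), and 4 of 6 naive genes, 6 adjusted over the list alone (4.69e-08; adjusted p = 0.27 with an estimated correlation). So were 2 of 6 type 17 genes, 3 adjusted over the list alone (2.39e-04; adjusted p = 0.264 with an estimated correlation), and 2 of 3 regulatory T cell genes by both counts (1.37e-04; adjusted p = 0.264 with an estimated correlation). The type 17 genes MAF (−1.20 ± 0.25) and KLRB1 (−0.65 ± 0.13) and the regulatory gene BATF (−0.84 ± 0.18) were lower in CD8. The other 10 lists had camera adjusted p from 0.0775 to 0.981, and the inhibitory (median 0.22, mean −0.07, test up), lipid (−0.08, 0.19, up) and tissue repair (−0.01, 0.16, up) lists differed in sign between measures.

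Of the chemokine genes CCL5, at 2858 against 1291 CPM (1.12 ± 0.11), CCL4L2 (1.89 ± 0.24) and XCL2 (1.42 ± 0.23) were higher in CD8, while LTB was lower (−1.52 ± 0.16). LGALS3 (1.13 ± 0.18), the fatty acid binding protein FABP5 (1.77 ± 0.33) and the chloride channel gene CLIC3 (2.28 ± 0.27) were higher in CD8. CD28 (−2.38 ± 0.36), DPP4, which encodes CD26 (−1.89 ± 0.24), CTSB (−1.78 ± 0.22), NOSIP (−1.70 ± 0.20), TNFSF10 (−1.41 ± 0.24) and LIMS1 (−1.36 ± 0.28) were lower. Of 6373 genes 68 passed in edgeR, 35 higher and 33 lower in CD8. The count was 162 without donor 2, 173 without donor 3, 29 without the donor block, 36 by DESeq2, 179 without the filter on low counts and 33 with equal cell numbers.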

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

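Of the tests in this part, the comparisons with islets were chosen only after the data were seen.

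Changes between the pancreas and another tissue differed between CD8 and CD4 T cells for few genes, by an interaction test over 7317 genes in edgeR, and the genes given here were named after their values were seen. Against the spleen 7 genes differed, 1 of them a receptor gene that is not named. LEF1 (CD8 −4.88, CD4 −1.70; adjusted p = 0.0296) and MAL, on 1 pancreas CD8 UMI, fell further in CD8. CEBPD changed in CD4 alone (CD8 0.09, CD4 4.81; adjusted p = 0.0028), P2RX5 lay at −1.67 in CD8 and 0.94 in CD4 (adjusted p = 0.0114), and CCR9 rested on 0 pancreas and 8 spleen UMIs in CD8. Against the pancreatic lymph node 2 genes differed, MAL among them. Against the small intestine 3 genes differed, a receptor gene, RUNX2 (CD8 3.35, CD4 0.02; adjusted p = 5.38e-04) and CCL20 (adjusted p = 5.38e-04), which had 39 pancreas and 38 small intestine UMIs in CD8 against 8 and 283 in CD4.

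T cells with the islets label were set against the pancreas after the other tissues. Between pancreas and islets 3 genes passed in CD8 T cells, all lower in the pancreas: ATF3 (−3.32 ± 0.49, adjusted p = 0.0127), NR4A2 (−2.12 ± 0.35, adjusted p = 0.0218) and RASD1 (−1.49 ± 0.24, adjusted p = 0.0218). In CD4 T cells 2 genes passed, CXCR6 at 201 against 66.9 CPM (1.60 ± 0.28, adjusted p = 0.0209) and BAG3, a heat shock cochaperone, at 67.2 against 409 CPM (−2.74 ± 0.47, adjusted p = 0.0209). These counts of 3 and 2 were 0 and 0 without the donor block, 64 and 24 in a fit of these 2 tissues alone, 61 and 36 without the filter on low counts, and 1 to 20 and 0 to 8 with a donor left out. Other splits of the 6 sums gave up to 11 genes in CD8, where 2 of 10 splits gave as many as the real one, and up to 5 in CD4, where 4 of 10 did; 10 splits are too few for a share under 0.05. Among the 4 splits that part every donor's pair, the highest other count was 0 in both subsets.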

How the results depend on the processing

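Summing islets into the pancreas, requiring CD4 evidence, leaving tags out of the CD8 share, using the EL hashtag alone and all comparisons with islets were chosen after seeing the data; the other alternatives were fixed before. Of the main results, 233 values under an alternative stayed within 1.5 times of a count or 1 SD of a share and 74 did not. Shares with 1 of the 3 donors left out are among the 233, and by arithmetic they cannot move by 1 SD. Of the values of named genes and proteins, 3587 kept their direction and their side of the threshold, 404 lost significance, 11 gained it and 5 reversed. Where no cause is given, the cause was not tested. In simulations with 1 preset spread, changes of 1 on the log2 scale were recovered for at most 23.4% of changed genes. Depth was not varied apart from the number of donors and their spread, so its part is not known. Spleen and pancreas CD4 sums were small.

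Without the donor block, which ignores the pairing, counts were 130 (CD8 against spleen), 733 (CD8 against small intestine), 175 and 381 (CD4 against the same), 29 (CD8 against CD4) and 0 and 0 (islets, CD8 and CD4); the pairing changed no other count of genes, proteins or lists by over 1.5 times, and 252 of 309 named calls held. Fits of 2 tissues with the donor block gave 146 and 453 genes in CD4 against spleen and small intestine, and 64 and 24 against islets.

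Leaving out each donor in turn gave 30 to 227, 275 to 847 and 397 to 1634 genes in CD8 against spleen, lymph node and small intestine, 119 to 241, 349 to 852 and 107 to 646 in CD4, 46 to 173 in CD8 against CD4, and 1 to 20 and 0 to 8 against islets. Proteins ranged from 14 to 26, 7 to 15 and 1 to 13 in CD8 and from 6 to 11, 5 to 20 and 4 to 16 in CD4. Fewer donors lower the power by construction. Named calls held in 204 of 303 cases without donor 1, 273 of 308 without donor 2 and 254 of 307 without donor 3. MS4A1 in CD8 against lymph node ranged from −0.44 (without donor 1) to 2.28.

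Equal cell numbers per tissue, which use fewer cells, gave 173, 450 and 321 genes in CD8, 207, 513 and 283 in CD4, 33 in CD8 against CD4, 0 in CD4 against islets, and reversed MS4A1 against lymph node (−1.16). No filter on low counts gave 544 genes in CD8 against spleen, 179 in CD8 against CD4 and 61 and 36 against islets. DESeq2's Wald test gave 36 in CD8 against CD4 and 6 and 0 against islets.

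Subsets by transcripts alone left 1 donor with pancreas CD4 sums, assumed to vary like the other groups, and no value for CD8 against CD4. They gave 29, 182 and 191 genes and 1, 6 and 9 proteins in CD4, 0 genes against islets, CD8 share differences of 33.1 and 32.2 points from spleen and lymph node, and TNFRSF4 in CD4 against spleen reversed to 0.37. Requiring CD4 evidence gave 176 genes in CD4 against spleen, with 2 donors in the pancreas. It left 1 donor with an islets CD4 sum, so no count is given for islets. Leaving out second-lineage cells gave 1 gene in CD4 against islets and reversed MS4A1 in CD8 against spleen to 0.14; summing islets into the pancreas reversed CD79A in CD8 against small intestine to 0.32. Centred log-ratios gave 9 proteins in CD4 against spleen.

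With an estimated correlation 0 lists passed in each of the 6 tissue comparisons (camera 10, 9 and 3 in CD8; 12, 8 and 8 in CD4), and fry gave 1 for CD8 against small intestine and 7 for CD4 against spleen. Tag-positive shares stayed within 1 SD under every alternative run, a wide bound here. With 1 donor left out they could not move by 1 SD. CD69 on CD8 T cells against spleen lay at −5.99 points with thresholds raised 1.5 times and −20.9 after thinning.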

Other observations

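Tests chosen only after the result was seen were those of the CD45 tag, of a shared stress response, of handling after the digestion, of a lower activation and of both MS4A1 explanations, and all comparisons with islets.

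T cells with the islets label held a lower CD8 share than those of the surrounding pancreas, 63.0% ± 15.5 against 81.1% ± 9.44 (SD, n = 3), a difference of 18.1 ± 10.8 points with the same sign in every donor (exact sign-flip p = 0.25, the smallest possible). The difference was 12.0 points without donor 1, 6.63 with subsets by transcripts alone and 5.35 with CD4 evidence required. Immediate early and heat shock genes were lower in the pancreas by camera, but not with an estimated correlation. In CD8 T cells 2 of 22 members were lower in the pancreas over all genes and 18 adjusted over the list alone (median −1.32; camera adjusted p = 8.32e-17, adjusted p = 0.222 with an estimated correlation). In CD4 T cells none passed over all genes and 9 adjusted over the list alone (1.44e-05; adjusted p = 0.874 with an estimated correlation). The list took 33334.5 ± 21660 CPM of CD8 T cells of the islets and 12566 ± 6310 CPM of those of the pancreas (SD, n = 3). Antigen presentation genes had a median of −0.63 in CD8 (0.0246; adjusted p = 0.457 with an estimated correlation), with none of 8 past the threshold by either count. Of 137 surface proteins edgeR called 0 in each subset, with 0 in CD8 and 9 in CD4 at an unadjusted p under 0.05, and no other tool was run on them.

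Some antibody tags of pancreas T cells were low against their transcripts. There were 60 tag and gene pairs in CD8 and 53 in CD4, without the genes that define the cells. In 14 of these the tag lay more than 1 log2 below the gene's change from the spleen in every donor, against 7 for the small intestine. Fewer antibody counts per pancreas cell are argued against by the CD45 tag, whose median per CD8 T cell in the pancreas was at least 1.2 times that of the spleen in each donor. A loss of epitopes in the enzyme digestion was given a bound of 2 times the other count, and 14 just meets it. Islets, which share the digestion, had 6 pairs in CD8 and 8 in CD4. CD2, CD27, CD81 and CD99 count in both subsets of the pancreas, while no small intestine antigen counts in both. With each antigen counted once the bound would not be met. In CD8 alone the pancreas had 7 pairs against 2 in the small intestine, and in CD4 alone 7 against 5. The count therefore cannot decide on this loss. Less protein per transcript as a property of the tissue stays open, since no undigested pancreas was measured and the mean CD2 tag of donor 1 differed 0.918-fold between crude and exocrine preparations. The CD103 tag differed more between these preparations, with means of 102 counts in crude and 48.8 in exocrine CD8 T cells. CD69 was not among the 14 pairs, and neither explanation was tested for its low tag share.

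Immediate early genes were low in pancreas T cells against spleen, lymph node and small intestine, where 11, 15 and 14 of 15 members were lower in CD8 and 12, 14 and 14 in CD4. Against islets 2 of 15 were lower in CD8 and none passed in CD4. A single stress response of cell isolation would move heat shock genes the same way, but in CD8 T cells their median lay 1.06 ± 0.592 above the spleen (SD over donors) while that of the immediate early members lay at −1.99 ± 0.485. In CD4 the heat shock median, 0.60 ± 0.717, was within its spread. Against lymph node, small intestine and islets the heat shock medians fell on the same side as the immediate early ones, at −0.69 ± 1.53, −1.03 ± 1.28 and −1.41 ± 0.477 in CD8 and −0.74 ± 1.33, −1.07 ± 0.855 and −1.39 ± 0.223 in CD4, so that a shared response stays open. Handling after the digestion stays open too: crude and exocrine pancreas CD8 T cells of donor 1, from 1 organ, differed 0.679-fold in immediate early CPM (2502 against 3685), short of the 1.5 times set for it. The test first planned, on the whole list with heat shock genes, passed that bound (4878 against 8209 CPM). For immediate early genes both preparations lay far below the 16198 CPM of the spleen of this donor, and this is 1 donor. A lower activation in the tissue itself cannot be told apart from the preparation: immediate early genes also lay −1.11 ± 0.365 below those of the islets of the same donors, and each tissue had 1 protocol.

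MS4A1, the B cell gene for CD20, was higher in CD8 T cells of the pancreas than of the small intestine (23.4 against 3.86 CPM; 2.82 ± 0.48), while CD79A was not (−0.30 ± 0.60, adjusted p = 0.788). Against spleen (−1.08 ± 0.52, adjusted p = 0.297) and lymph node (0.26 ± 0.55, adjusted p = 0.839) MS4A1 did not pass. RNA or doublets from B cells would keep the ratio of MS4A1 to CD79A found in B-like cells of the library, but it was 13.7, 3.27 and 17.5 times as high in donors 1, 2 and 3, with lower 95% bounds of 9.48, 0.697 and 3.62, so that donor 2 leaves it open. Expression by the T cells stays open as well: 10.8%, 3.82% and 2.85% of pancreas T cells held MS4A1 and no other B cell transcript, a share above both lymph node and small intestine with intervals apart in 2 donors, but not in donor 2. The share was not particular to the pancreas, since in donor 1 the spleen had 10.1% (95% interval 5.48 to 16.6) and the islets 11.4%. Median depth was lower in the pancreas (2340, 2325 and 2691 UMIs) than in the lymph node (3104, 3150 and 3194), and its effect on this share was not tested. Barcodes with at most 40 gene UMIs, taken as cell-free RNA of the library that all tissues of a donor share, held MS4A1 at 540, 328 and 262 CPM and CD79A at 605, 356 and 398 CPM. Pancreas T cells held MS4A1 at 52.7, 15.7 and 10.5 CPM of their UMIs, with 9.87, 2 and 4.5 MS4A1 UMIs per CD79A UMI, so that background may supply single UMIs but would bring more CD79A than was found in donors 1 and 3, whose lower 95% bounds were 6.81 and 0.931, while donor 2 (0.427) leaves this open.

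Other splits of the 6 sums into groups of 3 were refitted for each comparison. In every comparison between tissues other than the islets, and in CD8 against CD4, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The highest other counts were 6 (real 330), 8 (1011) and 0 (1231) for CD8 genes against spleen, lymph node and small intestine, 0 (397), 0 (1088) and 22 (727) for CD4 genes, and 1 (68) for CD8 against CD4. For proteins the highest other count was 0 in all 6 comparisons. Among the 4 splits that part every pair, it was 9 for CD4 genes against the small intestine, 1 for CD8 against CD4 and 0 elsewhere.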
